A study of Rattus norvegicus with 6 samples.

How the data were processed

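Small RNA libraries were made from small extracellular vesicles of rat plasma, 3 from control and 3 from diabetic rats. Per the labels' protocols, total RNA was extracted with TRIZOL, adaptors were ligated to both ends, and the amplified products of RNA of 18 to 30 nucleotides were selected by electrophoresis and sequenced on an Illumina HiSeq 2500. The genome build was rn6, per the submitters' processing notes. The aligner, the counting tool, the miRNA annotation release, the treatment of reads that match several miRNAs and the read filters were not given in the sources used here. Members of families with near-identical sequences, such as let-7, miR-30, miR-23a and miR-23b, miR-27a and miR-27b, and miR-450a and miR-450b, can share reads, so that their single values are uncertain. Among the tested entries, 7 in 3 groups had identical counts in all 6 libraries (let-7a-1-3p with let-7c-2-3p, miR-466b-2-3p with miR-466b-4-3p, and miR-3084a-3p with miR-3084b-3p and miR-3084d), and each entered the tests as its own entry. PCR duplicates cannot be told from separate molecules, and intervals and detection limits cover counting error only.

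Groups and replicate numbers came from the sample titles and treatment labels. Nothing in the labels states that each library came from a separate animal, so p-values measure the spread between these samples, which may in part be technical. The replicate numbers are shared between the groups without a stated link, and the fit was made without a block. Pairwise chi-square tests of the counts gave at least 795.8 per degree of freedom within groups, far above sampling noise, so that no library was a copy of another.

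The authors deposited 2 tables. Both hold whole-number counts per mature miRNA for the 6 libraries, and the deposited counts were identical in all 4584 cells. The second table also holds CPM values by the authors, which were recomputed from the counts in all 4584 cells within 0.006. The authors' log2 fold change is the log2 ratio of their mean CPM in diabetic over control libraries, with a mean of 0 replaced by 0.001, and was recomputed from the deposited means within 1e-06 for all 764 miRNAs. The authors' p-values and false discovery rates are of a test that the table's name gives as edgeR, while the series text names DEGseq. The false discovery rates of 566 miRNAs lay within 1e-06 of the Benjamini-Hochberg adjustment of the deposited p-values over these. All deposited columns of values matched a sample or were the authors' comparison.

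The counts as deposited were used for every test here. Totals ran from 6254077 to 8930730 per library. Of the 764 listed miRNAs, 198 had no count in any library. filterByExpr at its defaults (minimum count 10, minimum total count 15) kept 362 miRNAs with 99.993% of counts. Libraries were scaled by TMM (log ratio trim 0.3, sum trim 0.05), with factors of 0.802, 0.978 and 0.702 in control replicates 1, 2 and 3 and 1.27, 1.27 and 1.12 in diabetic replicates 1, 2 and 3. The test of diabetic against control was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Standard errors of log2 fold changes were the size of the fold change divided by the square root of the F statistic. Normalized CPM are counts divided by the TMM-scaled library size, on the scale of CPM. They are relative levels and not amounts per volume of plasma, and they differ from shares of the miRNA counts by each library's TMM factor. Percent values are shares of each library's deposited counts and were compared with a two-sided exact permutation test, whose smallest p is 0.1 with 3 libraries against 3.

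Before the data were examined, the groups, the tests, most alternatives, the rule for named miRNAs and 16 miRNA lists were fixed. The lists were erythrocyte-enriched, platelet-enriched, leukocyte-enriched, liver-enriched, heart and skeletal muscle, pancreas-enriched, endothelium-associated, neuron-enriched, epithelium-enriched, smooth muscle and fibroblast, the let-7 family, the miR-17-92 cluster and its paralogs, the miR-30 family, glucose and insulin metabolism, a circulating diabetes signature recalled from the literature and not checked against a publication, and the imprinted Dlk1-Dio3 cluster. A listed miRNA entered with both arms, and lists overlap. Each list was tested with limma's camera (limma 3.58.1) on log2 CPM (prior count 2) with a preset correlation of 0.01, and beside it with an estimated correlation and with fry, adjusted over the 16 lists. For single members an adjusted p was also computed over the list alone. The named miRNAs were the 5 with the highest mean CPM, up to 12 called miRNAs per direction with the largest changes and no overlap between groups, the 10 with the smallest p if these were fewer than 10, and up to 3 members of each list with the smallest p, 51 in all. miRNAs outside this rule are said to be chosen after their values were seen. Names are given without the species prefix of the files.

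Alternatives were RLE, upper quartile and library-size-only scaling, no filter beyond 1 count, a stricter filter of 10 CPM in 3 libraries, the 5 most abundant miRNAs left out of the scaling, DESeq2 1.42.0, edgeR's exact test, limma-voom, robust quasi-likelihood, Fisher's exact test on pooled counts, the replicate number as a block, an absolute log2 fold change of at least 1, and leaving out each library in turn. Another 3 combinations were added after the data were seen: the exact test with library size only and no filter, DESeq2 with library size only, and library size only without the 5 most abundant miRNAs. DEGseq was not used here.

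The steps were tested on simulated data for the comparison of diabetic with control libraries, with counts for the 362 tested miRNAs drawn from the libraries' own means and sizes. With 200 miRNAs changed, the quasi-likelihood test recovered 17.6% of 2-fold, 86.4% of 4-fold and 93.9% of 8-fold changes and called 2.5% of unchanged miRNAs. With 40 changed it recovered 0%, 64.3% and 91.7% and called 0.3% of unchanged miRNAs, and with none changed it called 0%. Each miRNA had a single mean over both groups, and changes up and down were balanced. The simulation thus held no shift in scaling between the groups and no library unlike its group. Its rates may not carry over to the real libraries. A table of rat genes on the assembly GRCr8, another build than the authors', was used for miRNA gene names and neighbourhood alone, and matched 334 of the 362 tested miRNAs to a single gene, so that no coordinates are given. Tables and figures were made with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.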

Results

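Small extracellular vesicles are membrane-bound particles that cells release into blood and other fluids, and they carry microRNAs (miRNAs), short RNAs that repress messenger RNAs. They were purified from 2 ml of plasma of male Sprague-Dawley rats, an outbred laboratory strain, aged 6 to 8 weeks when obtained, and their RNA of 18 to 30 nucleotides was sequenced. The 3 libraries of the control group came from control rats. The 3 libraries of the diabetic group came from rats given streptozotocin, a toxin of the insulin-producing beta cells of the pancreas, at 65 mg/kg, and were taken at 8 weeks of diabetes, defined by a fasting glucose above 11.1 mmol/L. The count table listed 764 mature rat miRNAs, of which 566 had at least 1 count. Total miRNA counts were 8930730, 6254077 and 6539603 in control replicates 1, 2 and 3, and 7490383, 7598853 and 8403856 in diabetic replicates 1, 2 and 3. A count of 0 in a single library allowed a level of up to 0.336 to 0.48 CPM (counts scaled to a library total of 1e+06), depending on the library, for counting error only.

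The plasma vesicle RNA of both groups was dominated by miR-148a-3p, a miRNA abundant in liver and B cells. It made up 36.4% ± 10 of miRNA counts in control and 30.5% ± 2.14 in diabetic libraries (mean ± SD, n = 3 each). The erythroid miR-486 made up 9.93% ± 6.28 and 6.88% ± 1.93, the hepatocyte miRNA miR-122-5p 7.68% ± 7.48 and 5.59% ± 1.16, and miR-128-3p, which is enriched in neurons, 5.06% ± 0.623 and 2.86% ± 2.67, in the same order of groups. The smooth muscle miRNA miR-143-3p took 1.74% ± 0.311 of counts in control and 5.54% ± 1.61 in diabetic libraries, and every diabetic library lay above every control library. Together these 5 miRNAs held 60.8% ± 4.26 of counts in control and 51.3% ± 3.63 in diabetic libraries, again without overlap between the groups. A two-sided exact permutation test gave p = 0.1 for miR-143-3p and for the 5 together, the smallest p that 3 libraries against 3 can give, and p = 0.4, 0.7, 0.9 and 0.4 for miR-148a-3p, miR-486, miR-122-5p and miR-128-3p. The 16.2% share of miR-122-5p in control replicate 3, against 2.1% and 4.75% in the other controls, set the control mean of that miRNA, and its log2 fold change of -1.15 became 0.27 without that library.

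**Figure D1:**
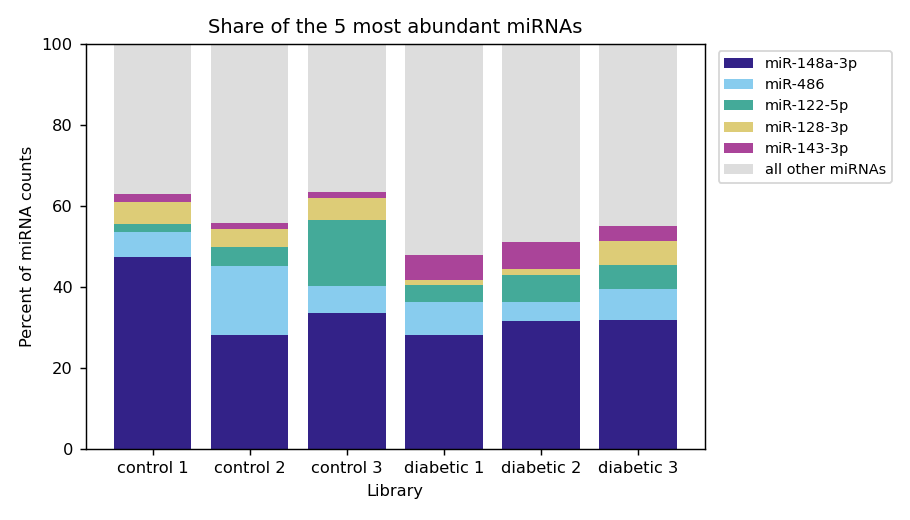
Percent of miRNA counts (vertical axis) taken by each of the 5 most abundant miRNAs and by all others in each of the 6 libraries (horizontal axis). The 5 miRNAs together took 55.9% to 63.5% of counts in the control libraries and 47.8% to 55.0% in the diabetic libraries.

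The comparison of diabetic with control libraries addressed which vesicle miRNAs differ at 8 weeks of diabetes. Of 362 miRNAs tested, 2 rose and 4 fell. miR-100-5p, which represses the growth kinase mTOR, rose from 641 ± 20.8 normalized CPM in control to 2355 ± 778 in diabetic libraries (mean ± SD, n = 3 each), a log2 fold change of 1.88 (SE 0.36). miR-532-5p, which is encoded in an intron of the chloride channel gene Clcn5 together with miR-362, miR-500 and miR-501, rose from 243 ± 55.0 to 755 ± 49.3 normalized CPM, a log2 fold change of 1.63 (SE 0.33). miR-671 fell from 124 ± 56.9 to 25.2 ± 5.04 normalized CPM, miR-130b-5p from 47.4 ± 19.1 to 9.94 ± 2.93, miR-6216 from 42.4 ± 22.7 to 9.38 ± 1.81 and miR-674-3p from 664 ± 251 to 152 ± 62.1. Their log2 fold changes were -2.30 (SE 0.44), -2.25 (SE 0.44), -2.17 (SE 0.47) and -2.12 (SE 0.45). In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p was 0.0418 for miR-100-5p, miR-532-5p, miR-671 and miR-130b-5p and 0.0483 for miR-6216 and miR-674-3p. For each of these 6 miRNAs all 3 libraries of one group lay above all 3 of the other.

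The 4 miRNAs next in order of p did not pass the threshold, with an adjusted p of 0.0647 each in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, although their groups did not overlap either. miR-217-5p, a miRNA of pancreatic acinar cells, stood at 2.57 ± 0.751 normalized CPM in control and 19.4 ± 16.9 in diabetic libraries (mean ± SD, n = 3 each), a log2 fold change of 2.91 (SE 0.68), or 1.94 without diabetic replicate 2. The cartilage miRNA miR-140-5p stood at 84.0 ± 33.1 and 288 ± 116 normalized CPM (log2 fold change 1.78, SE 0.43). miR-1247-5p stood at 4.6 ± 2.8 and 0.63 ± 0.189 normalized CPM (log2 fold change -2.82, SE 0.68), close to the detection limit in the diabetic group. The abundant miR-151-3p, encoded in an intron of the focal adhesion kinase gene Ptk2, stood at 46067 ± 5871 and 17470 ± 3287 normalized CPM (log2 fold change -1.40, SE 0.34).

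**Figure D2:**
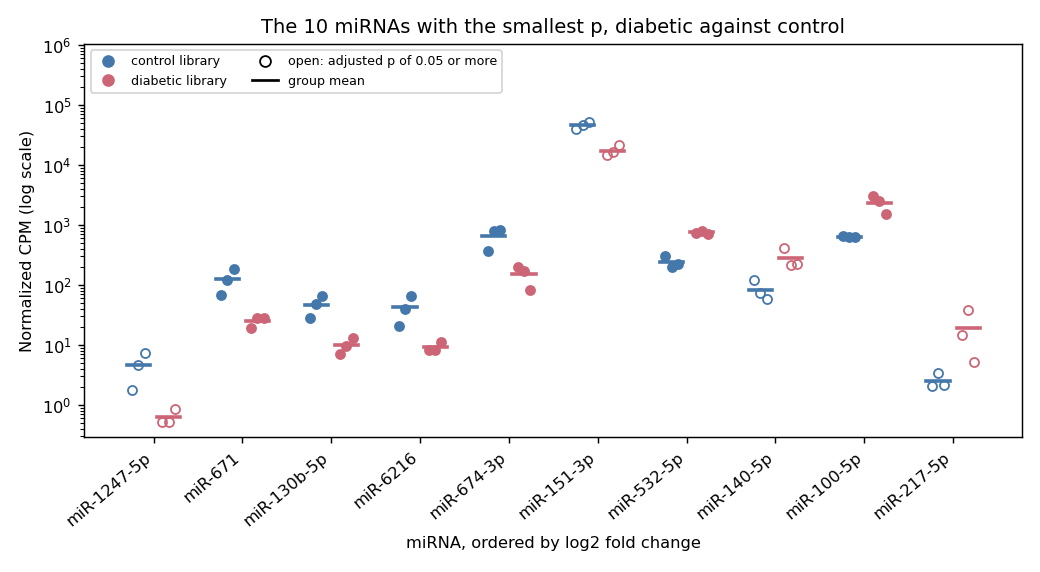
Normalized CPM on a log scale (vertical axis) of the 10 miRNAs with the smallest p (horizontal axis) in each control and diabetic library, with group means as lines; open points mark the 4 miRNAs with an adjusted p of 0.0647. For all 10 miRNAs the control and diabetic libraries did not overlap.

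At an unadjusted p under 0.05 there were 82 miRNAs, 40 higher and 42 lower in diabetic libraries, where chance alone gives 18.1. The groups were fully separated for 101 of the 362 miRNAs (27.9%), where chance gives 10%. miRNAs of one library are not independent, so neither excess is a test of the groups. The split with control replicate 1 and diabetic replicate 3 exchanged gave 58 at an unadjusted p under 0.05 in the same edgeR test and 65 separated (18.0%). The common biological coefficient of variation was 0.435. The number of calls rested on single libraries and on the test: edgeR's quasi-likelihood test called 49 miRNAs without control replicate 1 and 22 without diabetic replicate 3, and 0 without control replicate 2, control replicate 3, diabetic replicate 1 or diabetic replicate 2, where 57 to 59 miRNAs had an unadjusted p under 0.05. DESeq2 called 42 miRNAs (18 higher, 24 lower), edgeR's exact test 27 (12 higher, 15 lower) and limma-voom 4 (2 higher, 2 lower), and both DESeq2 and the exact test included all 6 miRNAs named above.

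Several other named miRNAs were called when 1 library was left out. Without control replicate 1 these were 6 higher miRNAs, with log2 fold changes of 2.86 for miR-379-5p, 2.14 for miR-223-3p, 2.11 for miR-140-5p, 2.03 for miR-145-5p, 1.69 for miR-138-5p and 1.22 for miR-143-3p, and 7 lower ones, at -3.23 for miR-1247-5p, -2.92 for miR-122-3p, -1.92 for miR-128-2-5p, -1.84 for miR-192-5p, -1.82 for let-7e-5p, -1.79 for miR-342-5p and -1.51 for miR-151-3p. Without diabetic replicate 3 they were 5 higher miRNAs, at 3.38 for miR-217-5p, 2.30 for miR-199a-5p, 1.97 for miR-140-5p, 1.97 for miR-145-5p and 1.39 for miR-126a-5p, and 3 lower ones, at -2.54 for miR-128-3p, -2.27 for miR-128-2-5p and -1.53 for miR-151-3p. Their adjusted p in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment ran from 0.00626 to 0.0447 and from 0.012 to 0.0486 in these fits.

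The direction of the calls depended on how the libraries were scaled to each other. With library size as the only scaling, the median log2 fold change of the 362 miRNAs was 0.61, against 0.02 with the trimmed mean of M values (TMM), -0.02 with relative log expression (RLE) factors and -0.28 with upper quartile factors. With library size only, 49 miRNAs passed the threshold, 45 higher and 4 lower, so that 91.8% of calls were higher, against 33.3% with TMM, 50% with RLE (2 higher, 2 lower) and 0% with upper quartile factors (0 higher, 2 lower). miR-100-5p and miR-532-5p remained among the 45, with log2 fold changes of 2.46 and 2.21. The 4 lower calls with library size only included miR-671, miR-130b-5p and miR-6216 at log2 fold changes of -1.72, -1.69 and -1.58, while miR-674-3p had an adjusted p of 0.0543 there in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. All fold changes given here without a named scaling are relative to the TMM median of 0.02, and the counts held no external standard that would fix the absolute level.

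**Figure D3:**
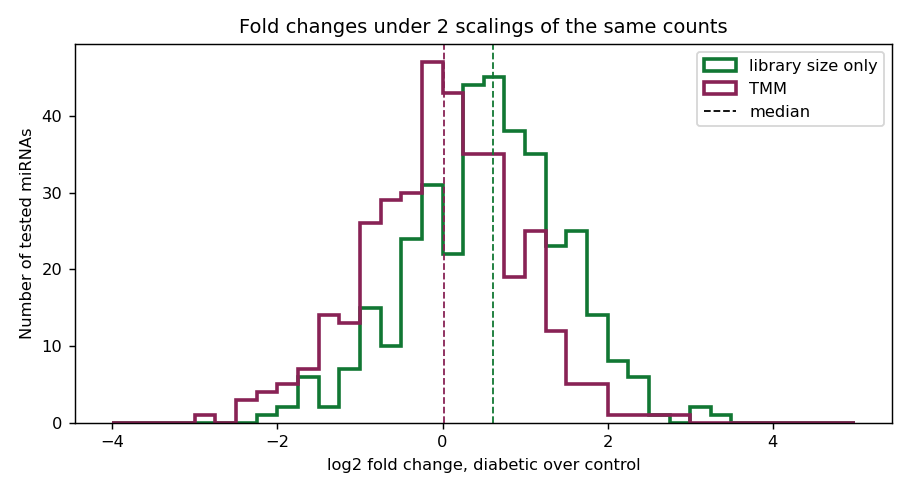
Number of tested miRNAs (vertical axis) by log2 fold change of diabetic over control (horizontal axis) under 2 scalings of the same counts, with dashed lines at the medians. The median lay at 0.61 with library size only and at 0.02 with TMM.

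**Figure D4:**
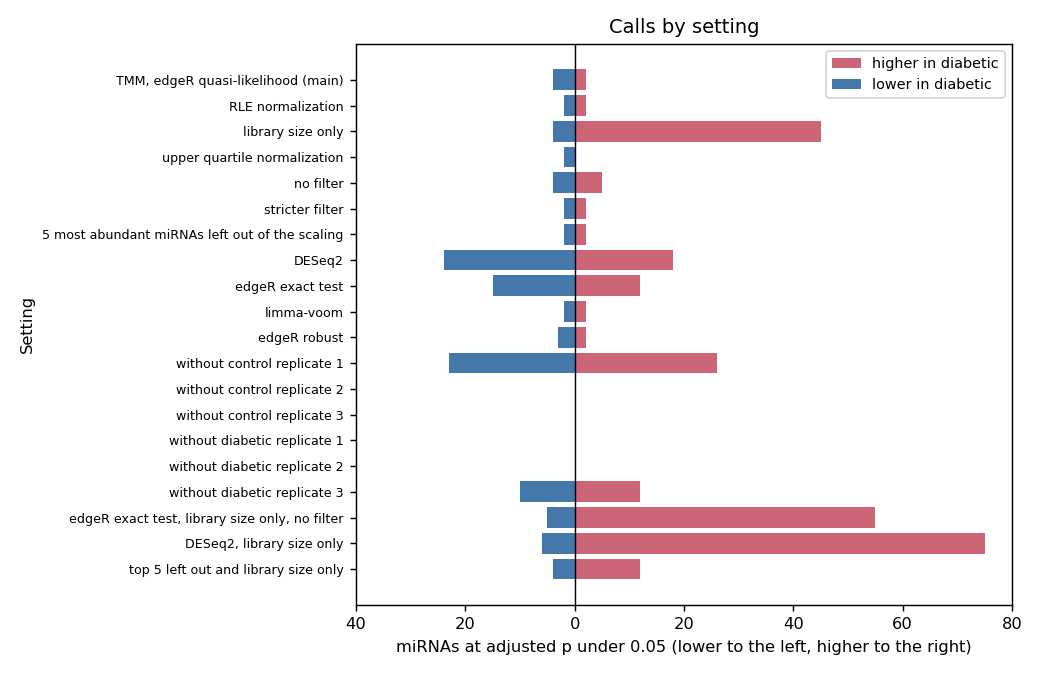
miRNAs with an adjusted p under 0.05 (horizontal axis, with higher in diabetic to the right and lower to the left) by setting (vertical axis). Fisher's exact test on pooled counts and the replicate block are not shown. The count was 6 with TMM and edgeR's quasi-likelihood test, 49 with library size only, and 0 when control replicate 2, control replicate 3, diabetic replicate 1 or diabetic replicate 2 was left out.

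The miRNA lists of blood cells, liver and other tissues were tested for a shared direction. No list passed limma's camera test, with an adjusted p of at least 0.778 with the preset correlation and at least 0.923 with an estimated correlation, n = 16 lists. With library size only, called members numbered 4 in the smooth muscle list, 3 each in the platelet, endothelium and glucose lists, 2 each in the miR-17-92, diabetes signature and Dlk1-Dio3 lists, 1 each in the leukocyte, heart and skeletal muscle, pancreas, neuron and miR-30 lists, and 0 in the erythrocyte, liver, epithelium and let-7 lists. All of these were higher in diabetic libraries except miR-130b-5p in the glucose list. Of the medians, the liver list's lay below 0 and the leukocyte list's above 0 under each of 5 scalings (TMM, library size only, RLE, upper quartile, and TMM with the 5 most abundant miRNAs left out). The median of every other list changed sign under at least 1 of these scalings, and the leukocyte median was 0.00087 with upper quartile factors. Control replicate 1 did not follow these directions: its mean log2 normalized CPM over the liver list was 8.10, below the 8.15 to 8.57 of the diabetic libraries, with 8.70 and 9.84 in control replicates 2 and 3, and over the leukocyte list it was 9.22, above the 8.91 to 9.05 of the diabetic libraries.

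Among blood cell miRNAs, none of the 14 erythrocyte, 11 platelet and 10 leukocyte miRNAs tested passed the threshold over all miRNAs, against 0, 3 and 1 with library size only, all higher. The erythroid miRNAs miR-451-5p, miR-486 and miR-363-5p had log2 fold changes of -1.33 (SE 0.40), -1.02 (SE 0.44) and -1.31 (SE 0.57), the last at -2.11 without diabetic replicate 2, while 8 of the 14 erythrocyte members lay above 0 and 6 below. In the platelet list miR-126a-5p stood at 1.19 (SE 0.35), miR-199a-5p at 1.87 (SE 0.59) and miR-191a-3p at -1.22 (SE 0.48), with 5 members above 0 and 6 below. In the leukocyte list, with 7 members above 0 and 3 below, miR-342-5p stood at -1.61 (SE 0.42) and was the 1 call adjusted over the list alone, against 0 in the erythrocyte and platelet lists. The inflammation-induced miR-146a-5p stood at 0.84 (SE 0.34), and the neutrophil miRNA miR-223-3p at 1.06 (SE 0.57), or 2.14 without control replicate 1, where it was called (adjusted p 0.00626 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The median, mean and camera direction of the erythrocyte list were 0.16, -0.05 and higher, and those of the platelet list -0.15, 0.17 and higher, so they differed in sign. Camera's p was 0.94, 0.761 and 0.527 for the erythrocyte, platelet and leukocyte lists. All 11 tested platelet members, 7 of the erythrocyte and 4 of the leukocyte members also belonged to another list.

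Among miRNAs of solid organs, the liver list had 6 of 8 tested members below 0 and a median log2 fold change of -0.89, or -0.33 with library size only, with 0 calls over all miRNAs. miR-122-3p, the passenger strand of the hepatocyte miRNA, stood at -2.45 (SE 0.67) and was the 1 call adjusted over the list alone. Its level was 17, 48.7 and 137 normalized CPM in control and 16.8, 11.7 and 8.49 in diabetic replicates 1, 2 and 3, so that control replicate 1 lay near the diabetic libraries, and the log2 fold change was -1.44 without control replicate 3. miR-192-5p stood at -1.38 (SE 0.56). In the pancreas list, 2 of 6 tested members lay above 0 and 4 below. miR-217-5p was the 1 call adjusted over that list alone, whereas miR-7a-2-3p and miR-7a-5p, both expressed in islets, stood at -1.94 (SE 1.31) and -0.48 (SE 0.40), the latter at 0.10 with library size only. miR-7a-2-3p had 2, 33 and 18 counts in control and 0, 0 and 23 in diabetic replicates 1, 2 and 3, so that diabetic replicate 3 held all counts of its group, and its log2 fold change was -1.29 without control replicate 2. The heart and skeletal muscle list had 3 of 7 tested members above 0 and 0 calls, with miR-499-5p at 0.77 (SE 0.39), miR-133b-3p at 1.02 (SE 0.56) and miR-133a-5p at -1.05 (SE 0.74), or -0.32 without control replicate 3. Its median of -0.09 differed in sign from its mean of 0.04 and from camera's direction, which was higher. The neuron list had 5 of 12 tested members above 0 and 0 calls, with miR-128-2-5p at -1.78 (SE 0.51), miR-132-5p at -1.91 (SE 0.61, or -1.30 without control replicate 3) and miR-138-5p at 1.12 (SE 0.45). The other arm of the miR-132 hairpin, miR-132-3p, stood at 0.41 and was chosen after its values were seen. The epithelium list had 6 of 10 tested members above 0 and 0 calls, with miR-429 at 0.83 (SE 0.45), miR-200b-5p at -1.17 (SE 0.63; -1.88 without diabetic replicate 3) and miR-203a-3p at 0.56 (SE 0.34). Camera's p was 0.123 for liver, 0.633 for pancreas, 0.512 for heart and skeletal muscle, 0.292 for neurons and 0.423 for epithelium.

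The vascular lists held members at both ends. Of 14 tested endothelium-associated miRNAs, miR-100-5p rose over all miRNAs, and miR-100-5p and miR-126a-5p were the 2 calls adjusted over the list alone. miR-126a-5p stood at 69.2 ± 8.55 normalized CPM in control and 157 ± 39.2 in diabetic libraries (mean ± SD, n = 3 each), and miR-27a-5p stood at a log2 fold change of -0.95 (SE 0.37). The list's median was 0.20, or -0.12 with upper quartile factors, with 8 members above 0. Of 13 tested miRNAs of smooth muscle and fibroblasts, 0 were called over all miRNAs, against 4 with library size only, all higher, and miR-145-5p was the 1 call adjusted over the list alone, at 174 ± 70.9 and 554 ± 273 normalized CPM (log2 fold change 1.67, SE 0.45). Its cluster partner miR-143-3p had a log2 fold change of 1.07 (SE 0.36) and an adjusted p of 0.121 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, or 0.0317 with library size only. The other arm of the miR-145 hairpin, miR-145-3p, stood at a log2 fold change of -0.71 and was chosen after its values were seen. The smooth muscle list's median of -0.11 differed in sign from its mean of 0.21 and from camera's direction, which was higher. Camera's p was 0.231 for the endothelium list and 0.768 for the smooth muscle list.

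Among miRNA families, 14 of the 18 tested let-7 members, which repress growth and cell cycle genes, lay below 0. The family's median log2 fold change was -0.42, or 0.14 with library size only. Of these members let-7a-1-3p and let-7c-2-3p had identical counts in all 6 libraries, and with that pair counted once 13 of 17 lay below 0, with medians of -0.42 and 0.14. let-7e-5p stood at -1.51 (SE 0.42), let-7d-3p at -1.20 (SE 0.39) and let-7c-1-3p at -1.45 (SE 0.55), with 0 calls over all miRNAs and 0 adjusted over the list alone. Camera's p of 0.0487 for this family did not survive Benjamini-Hochberg adjustment over the 16 lists (adjusted p = 0.778, and 0.923 with an estimated correlation). The miR-17-92 cluster and its paralogs, which promote proliferation, had 13 of 19 tested members above 0 and 0 calls, with miR-19b-3p at 1.12 (SE 0.36) and miR-93-5p at 0.82 (SE 0.36). The miR-30 family had 6 of 11 tested members above 0 and 0 calls, with miR-30a-5p at 0.69 (SE 0.33), miR-30b-5p at 0.84 (SE 0.50) and miR-30b-3p at 0.60 (SE 0.37). The imprinted Dlk1-Dio3 cluster had 18 of 28 tested members above 0 and 0 calls, with miR-379-5p at 1.86 (SE 0.63), or 2.86 without control replicate 1, miR-543-3p at -2.14 (SE 0.66) and miR-485-5p at -1.78 (SE 0.63), or -2.62 without diabetic replicate 2. Camera's p was 0.362 for the miR-17-92 list, 0.435 for the miR-30 list and 0.618 for the Dlk1-Dio3 list. The last 3 lists also had 0 calls adjusted over the list alone, as had the heart and skeletal muscle, neuron and epithelium lists.

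Of 16 tested miRNAs tied to glucose and insulin metabolism, miR-130b-5p fell and was also the 1 call adjusted over the list alone, and 7 members lay above 0 and 9 below. The other arm of the miR-130b hairpin, miR-130b-3p, stood at a log2 fold change of 0.06 and was chosen after its values were seen. miR-29c-3p, of the collagen-repressing miR-29 family, stood at -0.91 (SE 0.36). Of 21 tested miRNAs of a circulating diabetes signature, a list recalled from the literature and not checked against a publication, 9 lay above 0 and 12 below, with 0 calls over all miRNAs and 0 adjusted over the list alone, and miR-24-1-5p stood at -0.87 (SE 0.36). Camera's p was 0.556 and 0.61 for these lists. The mixed test of limma's fry, which asks whether the members of a list change in either direction without comparing them with other miRNAs, gave an adjusted p of 0.0123 for the endothelium list, 0.0259 for the smooth muscle, glucose and diabetes signature lists, 0.028 for let-7, 0.0439 for platelets and 0.0448 for erythrocytes, and of 0.0799 or more for the other 9 lists. Its test for a single direction gave an adjusted p of at least 0.842 for all 16.

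The authors' deposited table of the same comparison called 63 miRNAs at a false discovery rate under 0.05, 57 higher and 6 lower in diabetic rats. miR-100-5p and miR-532-5p were among its higher calls and miR-671, miR-130b-5p, miR-6216 and miR-674-3p among its lower calls, so that all 6 calls made here were also in the authors' deposited table. Of its 57 higher calls 55 were tested here, and all 55 had a TMM log2 fold change above 0, with a median of 1.20, and 39 had an unadjusted p under 0.05. Across the 362 tested miRNAs the Pearson correlation of the log2 fold changes in the authors' deposited table with those computed here was 0.999, and the authors' values lay higher by a median of 0.57. All 63 of the authors' calls were at least 2-fold, a change larger than that offset. The signs above 0 were thus nearly fixed in advance and do not test these calls. miRNAs are not independent replicates, and both sets of values come from the same counts. edgeR's exact test with library size as the only scaling and no filter, an alternative added after the table was seen, called 60 miRNAs (55 higher, 5 lower), all 60 of them among the authors' 63.

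Within groups, libraries resembled each other to different degrees. The Spearman correlation of normalized log2 CPM across miRNAs was 0.975 between control replicates 2 and 3, and 0.949 and 0.937 between control replicate 1 and these. Diabetic replicates 1 and 2 had a correlation of 0.98, and diabetic replicate 3 had 0.959 and 0.955 with them. Control replicate 1 correlated on average more with the diabetic libraries (0.957) than with the other controls (0.943), whereas each of the other 5 libraries correlated more with its own group. The miRNA miR-150-5p of lymphocytes stood at 3488 normalized CPM in control replicate 1, against 1000 and 700 in the other controls and 2324 to 3476 in diabetic libraries. This miRNA lies outside the rule for named miRNAs and was chosen after its values were seen.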

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

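The choice of these miRNAs followed from their values, and the tests that bear on them without the filter were planned. The filter on low counts left out 3 miRNAs that had 0 counts in all 3 control libraries and at least 3 counts in each diabetic library. In the authors' deposited table miR-216b-5p and miR-873-5p were called higher, at false discovery rates of 0.0003 and 0.0482, and miR-490-5p was not called (0.104). miR-216b-5p, a miRNA of pancreatic acinar cells, had 89 counts in the diabetic group, as 16, 65 and 8 in replicates 1, 2 and 3. With TMM-scaled library sizes that is at least 18.5-fold higher than a floor of 3 counts over the control group, which corresponds to 0.168 normalized CPM, or at least 7.54-fold without diabetic replicate 2, and its adjusted p without the filter was 0.0371 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. miR-873-5p had 16 counts in the diabetic group, as 6, 3 and 7, at least 3.33-fold higher than that floor, or at least 2.79-fold with any 1 diabetic library left out, with an adjusted p of 0.199 without the filter in the same edgeR test. miR-490-5p had 12 counts, as 3, 3 and 6, at least 2.5-fold higher than the floor, or at least 1.86-fold with any 1 diabetic library left out, with an adjusted p of 0.25 in the same edgeR test. No technical or biological explanation was tested for these 3 miRNAs, and groups of 3 libraries are too small for a test of single outlying libraries.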

How the results depend on the processing

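The alternatives with 2 choices changed together were chosen after the data were seen. The 6 calls (2 higher, 4 lower) became 49 (45 higher, 4 lower) with library size only, 2 (0 higher, 2 lower) with upper quartile factors, 42 (18 higher, 24 lower) with DESeq2, 27 (12 higher, 15 lower) with edgeR's exact test and 304 (236 higher, 68 lower) with Fisher's exact test on pooled counts, which ignores the spread between libraries. There were 9 (5 higher, 4 lower) without the filter, 5 (2 higher, 3 lower) with robust fitting, and 4 (2 higher, 2 lower) each with RLE factors, the stricter filter, the 5 most abundant miRNAs left out of the scaling, and limma-voom. Of the added settings, the exact test with library size only and no filter gave 60 (55 higher, 5 lower), DESeq2 with library size only 81 (75 higher, 6 lower, 1 adjusted p not given), and library size only without the top 5 gave 16 (12 higher, 4 lower). Leaving out 1 library gave 0 to 49 calls (0 to 26 higher, 0 to 23 lower), with 49 without control replicate 1, 22 without diabetic replicate 3 and 0 without any of the other 4. Fewer libraries enter each of those fits. The common biological coefficient of variation was 0.381 without control replicate 1 and 0.412 without diabetic replicate 3. It was 0.443 to 0.466 in the 4 fits with 0 calls and 0.435 with all libraries. The cause of the gain or loss was not tested. A minimum absolute log2 fold change of 1 removed none of the 6. The replicate block gave 57 calls (26 higher, 31 lower), with a common biological coefficient of variation of 0.39. The deviations of same-numbered libraries from their group means had correlations of 0.281, 0.001 and 0.246 for replicates 1, 2 and 3. Among all pairs of a control with a diabetic library, 0.281 and 0.246 were the highest values and 0.077 the next. Control replicate 2 correlated best with diabetic replicate 1 (0.064), not with its own number. The numbers were not taken as pairs, because the labels state no link between them, and whether they mark a pairing stays open.

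The lists had 0 camera calls under every setting run; DESeq2, the exact test and robust fitting do not enter camera, and the planned setting without predicted miRNAs was not run, because the deposited tables mark no entry as predicted. miRNAs at an unadjusted p under 0.05 both here and in the authors' deposited table were 52 (40 higher, 12 lower), against 6 called in both. For single named miRNAs, miR-122-5p ranged over log2 fold changes of -1.61 to 0.27 when libraries were left out, above 0 without control replicate 3. miR-7a-5p, at -0.48, stood at 0.10 with library size as the only factor in edgeR's quasi-likelihood test, the exact test and DESeq2, but at -0.20 when the top 5 were left out as well, and the cause was not tested beyond the scaling itself. Of the other results for named miRNAs, leaving out a library kept 260 on the same side of the threshold and in the same direction, brought 21 past it and took 24 back, and the other settings did so for 582, 106 and 14. Depth limited the miRNAs under about 10 counts per library, whose levels lie near the floor of 0.336 to 0.48 CPM.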

Other observations

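The tests of exchanged labels and of depth, the bootstrap interval, the median shift with single libraries left out and the cluster test without its largest cluster were chosen only after the results were seen, and the patterns themselves were noticed in these data. The genes of miR-216b, miR-216a and miR-217, miRNAs of pancreatic acinar cells, are neighbours in the rat genome. miR-217-5p had 15, 21 and 10 counts in control replicates 1, 2 and 3 and 141, 368 and 50 in diabetic replicates 1, 2 and 3. miR-216b-5p had 0, 0 and 0 against 16, 65 and 8, miR-216a-5p had 1, 0 and 3 against 8, 20 and 1, miR-216a-3p 2, 1 and 2 against 1, 13 and 3, and miR-216b-3p 0, 0 and 3 against 7, 11 and 0, so that the arms at the lowest counts did not separate the groups. The islet miRNA miR-375-3p differed within groups, at 897, 24778 and 40325 normalized CPM in control and 882, 1558 and 21644 in diabetic replicates 1, 2 and 3. miR-1224 (3.49, 62.0 and 82.1 against 2.41, 3.11 and 42.0 normalized CPM) and miR-504 (16.1, 69.0 and 115 against 4.09, 6.63 and 30.0) followed miR-375-3p. These miRNAs other than miR-217-5p were chosen after their values were seen, and no explanation was tested.

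The miRNA miR-532-5p belongs to a genomic cluster with miR-362, miR-500 and miR-501, and all 6 tested arms of that cluster lay above 0, 4 of them at an unadjusted p under 0.05, with a mean log2 fold change of 1.17 over its 4 hairpins. The hypothesis that miRNAs of one cluster change together arose from the authors' list of calls. It was tested on 122 pairs of hairpins within 10 kb from 30 clusters, leaving out pairs with the same number in their names. Pairs of one family with different numbers, such as let-7f-2 and miR-98 of the let-7 family, were kept. The mean absolute difference of log2 fold changes within pairs was 0.954, not smaller than the 0.941 when fold changes were reassigned to hairpins (one-sided permutation p = 0.5584, 10000 permutations). That result rested on the largest cluster, of 10 hairpins whose log2 fold changes ranged from -2.14 to 1.86: without it the difference was 0.75 against 0.942 over 85 pairs (permutation p = 0.0302). Since the cluster left out is one whose members disagree, the second value is no evidence of a tendency in the others. Over all pairs the permutation p missed the limit of 0.05 set before the test, so a shared change was not shown. A p above that limit does not exclude such a change, and the hypothesis stays open. The arms of 1 hairpin shared a sign in 52 of 95 hairpins (permutation p = 0.25), with a Pearson correlation of 0.236 and a Spearman correlation of 0.209 across hairpins (permutation p = 0.022 for the former), and hairpins are not independent replicates. In miR-340 both arms had an unadjusted p under 0.05 and opposite signs, at 0.92 for the 5p and -1.15 for the 3p arm.

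The median miRNA had a log2 fold change of 0.61 by library size alone and 0.02 after TMM. Within groups the level of the median miRNA changed by -0.015 on the log2 scale per doubling of the total count (-1.74 to 0.34 with 1 library left out), where a slope of 4.67 would be needed for the difference of 0.13 in mean log2 totals to give the shift. So steep a slope was needed because the totals hardly differed, which left the outcome of that test nearly fixed in advance. The small difference in totals, and not the slope, argued against depth as the main cause. The 25% of miRNAs with the highest levels had a median of 0.492 (95% bootstrap interval over miRNAs 0.373 to 0.783), above the limit of 0.303 set before the test was run, so low counts were argued against as the main cause. That interval covers the sampling of miRNAs, which are not independent replicates, and not the spread between libraries. Leaving the 5 most abundant miRNAs out of the library sizes lowered the median to 0.282, under the same limit, a drop set by their shares of 60.8% and 51.3%, but in ratios of mean CPM with 1 library left out 36.3% (without control replicate 2) to 59.8% (without control replicate 1) of the shift was left, on both sides of 50%, so these miRNAs may account for part of the shift and how large a part stays open. Diabetic libraries held 479 to 506 miRNAs with at least 1 count and control libraries 439 to 462, and a broader miRNA content of the vesicles of diabetic rats stays open as a biological explanation that was not tested.

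Control replicate 1 lay nearer the diabetic libraries than the other controls, with mean Spearman correlations of 0.957 and 0.943. On the first principal component, the axis of largest spread (52.6% of variance), that library lay at -2.3 and diabetic replicate 3 at -2.6. Control replicates 2 and 3 lay at 10.7 and 15.3, and diabetic replicates 1 and 2 at -12.1 and -9.0. Labels exchanged with a diabetic library were argued against, since 0 of 3 diabetic libraries correlated more with control replicates 2 and 3 than with their own group, although miR-375-3p, miR-1224 and miR-504 set diabetic replicate 3 nearer to those controls than to diabetic replicates 1 and 2 on the log scale, and the split with control replicate 1 and diabetic replicate 3 exchanged gave 6 calls, as many as the real one. Control replicate 1 alone being mislabelled may explain this and stays open: on a scale from the other controls (0) to the diabetic libraries (1) its median position was 0.673 over 62 miRNAs (interquartile range 0.389 to 0.93), above the 0.464 of diabetic replicate 3 and below the 0.989 and 0.825 of diabetic replicates 1 and 2, each over its own set of miRNAs, although among the 49 calls made without it this library lay between the ranges of both groups for 26 and within the diabetic range for 19. More blood cell RNA in control replicate 1 also stays open: 3 of 3 blood cell lists were higher there than in both other controls, with miR-223-3p at 851 normalized CPM against 192 and 189, but 6 of 13 other lists were higher as well, and miR-486, the most abundant erythroid miRNA, was lower there at 74691 against 175585 and 94284, while the erythroid miR-451-5p was higher at 12716 against 11609 and 5931. That test did not ask whether the diabetic libraries held more blood cell RNA too, so it cannot explain the nearness to them. The mean log2 normalized CPM of the leukocyte list was 9.22 there, 8.52 and 8.54 in the other controls and 8.91 to 9.05 in diabetic libraries. In the same order, the erythrocyte list stood at 6.88, 6.52 and 6.33, and 6.50 to 6.68. The platelet list stood at 8.74, 8.36 and 8.58, and 8.58 to 8.74. A difference between control animals was not tested.

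Of the 10 ways to split the 6 libraries into groups of 3, 2 gave at least 6 calls, the real split included, and the highest of the others gave 6. So few splits cannot give a share under 0.05. The other split set control replicate 1 with diabetic replicates 1 and 2, so that it differs from the real one by the exchange of control replicate 1 and diabetic replicate 3, and had 58 miRNAs at an unadjusted p under 0.05 and 65 fully separated, against 82 and 101 for the real split.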
